A study of Mus musculus with 6 samples.

How the data were processed

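Liver RNA from FVB mice aged 10 weeks was profiled on Illumina bead arrays after conversion to biotinylated cRNA, per the labels' protocols. The labels describe 6 samples, each a pool, in 6 groups of 1 array. LIXs mice carry an inducible transgene for Xbp1s, the spliced and active form of the transcription factor Xbp1, which doxycycline (Dox) switches on. A pool of LIXs and a pool of wild-type (WT) mice were taken after 24 h and after 48 h of Dox chow, all after 6 h without food, and 2 further WT pools came from mice fasted for 24 h or refed for 2 h. The number of animals in a pool is not given in the sources used here. With 1 array per group, the number of arrays limits the precision of every value.

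The authors deposited a value table with a linear intensity for each of 45281 probes on each array. GenomeStudio is the only tool named, per the submitters' processing notes, and the normalization method, its settings and the software version are not given in the sources used here. The deposited intensities ran from 81.1 to 50652 with a median of 113 on every array. On the log2 scale, each array's sorted values lay within 0.0199 of those of the array labelled LIXs at 24 h. They were therefore treated as already normalized between arrays and not background-subtracted. A second table with 6 unnormalized signal columns and 6 detection p columns was not used, because its column names match no sample. The design had assumed background correction from control probes and detection p-values, and the closest equivalent that the value table allows was used in their place.

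The background level was taken as the mode of all log2 intensities, 109 on the linear scale, with an SD of 7.67 from the values below the mode mirrored about it. Those parameters entered limma's normexp correction, an offset of 16 was added, and the arrays were quantile-normalized and put on a log2 scale with limma 3.58.1 in R 4.3.3. A probe counted as detected above an intensity of 129, the level that leaves a share of 0.01 of the mirrored background above it. Probe names came from the array's annotation, in which 34885 probes had 1 gene name, 18 had several and 10378 had none. Of the named probes, 34807 matched a gene of the reference table by its identifier, and 0 symbols needed an update. Each of the 19057 named genes was represented by its brightest probe, and probes with several names or none were left out. Among the named genes with other detected probes, 54 of 63 gene and comparison pairs had the same sign on all of those probes. The exceptions were Slc38a10 (averaged, at 24 h and between the LIXs arrays) and Hfe, Ngef, Sec22c and Arfip2 (refed against fasted). Nipal3 and Zfp933 were exceptions between the WT arrays at 48 h and 24 h.

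The difference between arrays labelled LIXs and WT was averaged over both times with limma's lmFit and eBayes on the 4 Dox arrays, with time on Dox as a block and Benjamini-Hochberg adjustment to 0.05. The fit covered genes detected on at least 2 of these arrays. It had 1 residual degree of freedom, to which limma's prior added 9.69 with a prior SD of 0.222, so the error of a difference holds pool, array and the change of the difference between times together. The arrays hold pools and not single animals, so p-values measure the spread between these arrays and not between animals. Through the prior, that spread is estimated mostly from all genes together. Fga, with a difference of 0 at both times, still had a standard error (SE) of 0.21. An SE of that size is therefore not the gene's own spread. On data simulated for this comparison with 7652 genes, of which 100 per size were changed, 80.4% of 2-fold and 100% of 4-fold changes were found over 5 runs. In those runs 17.5% of the calls were false, more than the adjusted p promises. Each simulated change was equal at both times, and errors were drawn independently per gene from the fitted prior. The shares need not hold for differences that change between times or for errors that genes of a pool share. Comparisons of 2 arrays had no test, and genes detected on at least 1 of them were counted at a difference of 2-fold. Where a gene was not detected on the dimmer array, its ratio is given as a lower bound: the bright signal over the higher of the lowest detected signal and the gene's own signal on the dim array.

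Gene lists of pathways, cell types, circadian and sex-biased genes, 34 in number with 591 genes, were fixed before the data were examined, as were the groups, the tests, the alternatives not described as added and the rule for naming genes. Of the list genes 539 had a named probe, and 3 stood in more than 1 list. A list's median difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, as a percentile that describes these arrays and is no p-value. Its 95% interval came from 2000 bootstrap draws of its genes. The interval describes the spread of those genes on these arrays and holds no variation between pools or arrays. Named genes were the 10 per direction past the limma test whose smaller difference of the 2 times was largest, with the same sign at both times and detection on all 4 arrays. For each comparison of 2 arrays they were the 10 per direction with the largest difference among genes detected on both, then up to 5 per direction by their lower bound. For the change between times they were the 5 per direction with the largest change. Xbp1 and members of the lists were also named, and genes known only by a clone or locus identifier were counted and not named.

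Alternatives covered no background correction, which is the deposited table on a log2 scale, an offset of 50, a mirrored share of 0.05 for detection, no filter on dim probes, the mean of a gene's probes, a 1.5-fold size, a fit without the time block, other variance priors, an adjusted p of 0.10, the omission of each Dox array and the addition of the fasted and refed arrays. Normexp parameters fitted by saddle point and the inclusion of unnamed probes were added after the data had been seen.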

Results

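Expression was measured on 6 Illumina arrays, each hybridised with pooled liver RNA of FVB mice. The groups were LIXs and WT at 24 h of Dox, LIXs and WT at 48 h of Dox, WT refed for 2 h and WT fasted for 24 h, with 1 array per group. Probes above the detection level numbered between 12127 and 12192 per array, and genes between 7471 and 7547. In total 10039 named genes were detected on at least 1 array. The series asked how induced Xbp1s alters liver gene expression.

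Xbp1, the induced gene, had nearly equal signal on all arrays. Its deposited intensity was 4537 and 4259 on the arrays labelled LIXs and WT at 24 h, and 4350 and 5210 at 48 h. The refed and fasted arrays read 5120 and 4457. The log2 difference between the arrays labelled LIXs and WT was 0.09 at 24 h and -0.27 at 48 h, with an average of -0.09 ± 0.22 (SE, limma adjusted p = 0.836). A single probe reports Xbp1, and where it lies relative to the transgene's sequence is not given in the sources used here, so it does not check the genotype labels. Because established Xbp1s target groups were lower on the arrays labelled LIXs, as described next, every direction in the text is that of the labels and is written as such.

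**Figure D1:**
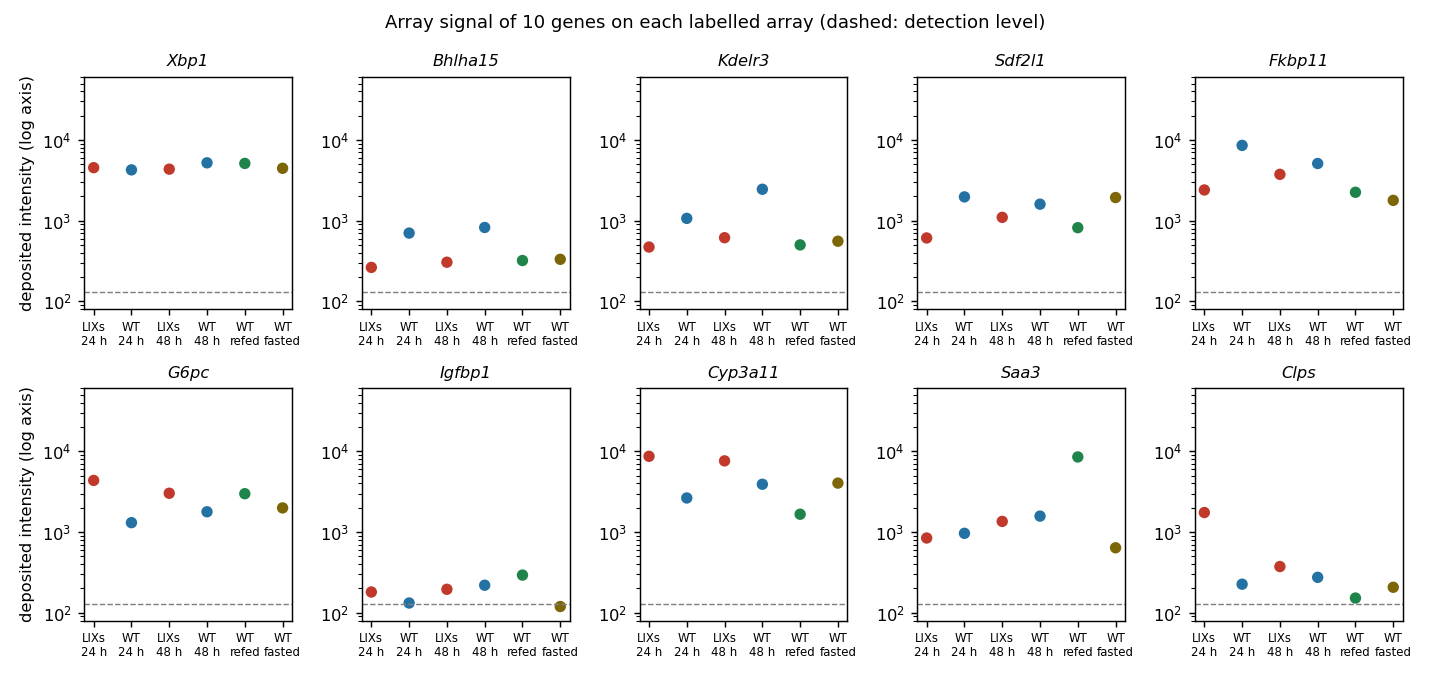
Deposited intensity (log axis, 1 point per labelled array) of 10 genes on the 6 arrays, with the detection level of 129 dashed. Xbp1 lay between 4259 and 5210 on all 6, whereas Kdelr3 read 472 and 1068 on the arrays labelled LIXs and WT at 24 h, and 615 and 2452 at 48 h.

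Genes of protein handling in the endoplasmic reticulum (ER), known targets of Xbp1s, were lower on the arrays labelled LIXs at both times. Of the 105 measured genes in 5 such lists, 100 had an averaged difference below 0, with a median of -0.55 (95% interval -0.65 to -0.45). Dnajc3, an ER co-chaperone, fell by 1.32 ± 0.22 on the log2 scale (SE, 2 arrays per genotype, adjusted p = 0.023), and Syvn1, the ubiquitin ligase of ER-associated degradation, fell by 1.21 ± 0.25 (adjusted p = 0.030). Kdelr3, a receptor that returns escaped ER proteins from the Golgi, fell by 1.77 ± 0.24 (adjusted p = 0.023). Bhlha15, a transcription factor of secretory cells also known as Mist1, fell by 1.81 ± 0.21, or 3.50-fold.

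By list, the counts of this averaged comparison were as follows. Among 20 ER chaperones and folding enzymes 4 fell and 0 rose, against 9 that fell when adjusted over the list alone. Sdf2l1 fell by 1.22 ± 0.29 and Fkbp11 by 1.17 ± 0.30, while Hspa5, the chaperone BiP, differed by -0.09 ± 0.22 (adjusted p = 0.815). The Hspa5 probe was dim on all arrays, so this value does not show an unchanged transcript. Of 14 genes of ER-associated degradation 5 fell (6 adjusted over the list alone), including Derl3 at -1.14 ± 0.22 and Edem2 at -0.94 ± 0.23. Of 22 genes of ER translocation, signal peptide cleavage and signal recognition 5 fell (13 adjusted over the list alone), among them Srprb at -1.09 ± 0.23 and Ssr1 at -0.86 ± 0.23. Among 30 genes of COPII, COPI and Golgi trafficking 11 fell (14 adjusted over the list alone), with Tmed3 at -1.37 ± 0.31, Arfgap3 at -1.32 ± 0.21 and Sec16a at -1.09 ± 0.24. For N-glycosylation 0 of 19 genes passed over all genes, and 5 fell when adjusted over the list alone, with Stt3a at -0.89 ± 0.27. The medians of these 5 lists were -0.58, -0.42, -0.69, -0.51 and -0.54, and their percentiles among random lists 0, 0.22, 0, 0 and 0.02.

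Other stress lists moved less uniformly. Of 16 targets of the PERK, ATF4 and CHOP branch 4 fell and 0 rose, against 4 that fell and 2 that rose adjusted over the list alone. The median was -0.34, at percentile 1.02. Ddit3, which encodes CHOP, fell by 1.36 ± 0.25 and Aldh18a1, an enzyme of proline synthesis, by 1.39 ± 0.28, whereas Trib3 differed by 0.78 ± 0.25 (adjusted p = 0.070). The median of 11 heat shock genes was 0.07 and that of 8 immediate early genes -0.27, with 0 genes past the test in either list, also adjusted over the list alone.

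Some liver genes of bile acid, xenobiotic and glucose metabolism were higher on the arrays labelled LIXs. Abcg8 and Abcg5, which together export sterols into bile, rose by 1.41 ± 0.21 and 1.19 ± 0.22, Abcb4 by 1.15 ± 0.23 and Abcb11, the bile salt export pump, by 1.01 ± 0.22. In that list of 14 genes 4 rose and 0 fell (9 rose adjusted over the list alone), with a median of 0.66 at percentile 100. Of 20 xenobiotic genes 7 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.59 at percentile 100. These included the drug-oxidising Cyp3a11 at 1.37 ± 0.24 and the xenobiotic receptors Nr1i3 at 1.19 ± 0.23 and Nr1i2 at 1.09 ± 0.24, while Srxn1 fell by 0.77 ± 0.21. G6pc, the glucose-6-phosphatase that releases glucose, rose by 1.30 ± 0.26 and Pck1 by 0.77 ± 0.21. They were the 2 of 14 gluconeogenesis genes that rose (3 adjusted over the list alone, 0 fell), with a median of 0.44 at percentile 99.7. Of 9 glycogen genes 2 rose (6 adjusted over the list alone, 0 fell), Ppp1r3c by 0.86 ± 0.22 and Ppp1r3b by 0.85 ± 0.22. The glycogen median was 0.60, with a 95% interval from -0.16 to 0.85, at percentile 99.9.

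In lipid metabolism, the lipogenic regulator Srebf1 rose by 1.17 ± 0.21, Pklr by 1.21 ± 0.28 and Fads2 by 0.87 ± 0.21. These were 3 of 15 genes of fatty acid and triglyceride synthesis (4 adjusted over the list alone, 0 fell), whose median of 0.22 stood at percentile 92.4. Sterol genes went the other way for Fdps, Dhcr7 and Lss, which fell by 1.07 ± 0.25, 0.85 ± 0.21 and 0.80 ± 0.22. They were 3 of 16 genes (3 fell and 2 rose adjusted over the list alone), with a median of -0.13 at percentile 16.8. Fatty acid oxidation and ketogenesis had 2 of 23 genes higher, Acot1 at 1.24 ± 0.28 and Plin5 at 0.77 ± 0.21 (4 rose adjusted over the list alone, 0 fell), with a median of 0.34 at percentile 99.6. Amino acid catabolism had 2 of 15 genes higher, Otc at 0.83 ± 0.21 and Bckdhb at 0.77 ± 0.21 (5 rose adjusted over the list alone), with a median of 0.45 at percentile 99.9. In phospholipid synthesis 1 of 15 genes rose and 1 fell (2 and 1 adjusted over the list alone), Chpt1 at 0.82 ± 0.21 and Lpin3 at -1.12 ± 0.23. In galactose and UDP-sugar metabolism 1 of 10 genes rose, Galm by 0.98 ± 0.21 (1 rose and 2 fell adjusted over the list alone).

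Some markers of other tissues and cell types also differed between the genotype labels. Pancreatic acinar genes had the largest median of all lists, 1.65 (95% interval 1.23 to 1.87), with 7 of 14 higher and 0 lower (11 higher adjusted over the list alone). That median came from the 24 h pair, as given below for that time. Female-biased liver genes rose in 6 of 8 cases (6 adjusted over the list alone), including Sult2a2 at 1.83 ± 0.39 and Cyp2b13 at 1.38 ± 0.26. Male-biased genes rose in 2 of 8 cases, Selenbp2 by 1.06 ± 0.24 and Hsd3b5 by 1.03 ± 0.22 (3 adjusted over the list alone). Car3, the 1 measured gene of the 9 in the adipocyte list, rose by 1.16 ± 0.26. On its own it does not show that adipose tissue differed. Clock genes rose in 2 of 11 cases (2 adjusted over the list alone), Ciart by 1.38 ± 0.21 and Tef by 0.88 ± 0.21. Hepatocyte secretory products had 2 of 17 genes higher, Rbp4 at 1.03 ± 0.23 and Serpinc1 at 0.83 ± 0.21 (2 adjusted over the list alone), and the acute phase list had 2 of 23, Saa4 at 0.99 ± 0.25 and Hamp2 at 0.87 ± 0.22 (3 adjusted over the list alone).

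Of the remaining cell types, the 11 sinusoidal endothelial markers had a median of 0.42 at percentile 99.4 with 0 past the test, also adjusted over the list alone. The neutrophil gene Mpo fell by 1.07 ± 0.21, as 1 of 3 (1 adjusted over the list alone). In the cholangiocyte list, the keratins Krt18 and Krt8 differed by -0.73 ± 0.21 and -0.65 ± 0.21, past the threshold only when adjusted over the list alone (2 of 3). The other measured gene, Sox9, differed by -0.35 and did not pass. Whole-liver RNA does not show which cell type these transcripts came from. Among 3 erythroid genes 0 passed over all genes, and 2 rose adjusted over the list alone, Alas2 at 0.72 ± 0.22 and Hbb-b2 at 0.56 ± 0.22. Medians of 10 macrophage, 8 stellate cell and 7 proliferation genes were 0.12, 0.13 and -0.18, and the 1 measured lymphocyte marker differed by 0.03, with 0 past the test in these lists, also adjusted over the list alone.

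Outside the lists, the largest repeated increases included Rgs16, a regulator of G-protein signalling, at 1.75 ± 0.24, and Depp1, a target of FOXO transcription factors, at 1.52 ± 0.21. Cpsf4l rose by 1.48 ± 0.23, Fn3k, a fructosamine kinase, by 1.39 ± 0.22, Extl1 by 1.37 ± 0.22, Abca8a by 1.37 ± 0.22, Mast3 by 1.32 ± 0.22 and the transporter Abcc6 by 1.18 ± 0.21. The largest repeated decreases included the transporter Slc38a10 at -1.83 ± 0.27, Ccdc134 at -1.77 ± 0.25, Exog, a mitochondrial nuclease, at -1.52 ± 0.23 and Cthrc1 at -1.51 ± 0.21. Lmna, which encodes lamins A and C, fell by 1.40 ± 0.21, the brain-type glycogen phosphorylase Pygb by 1.39 ± 0.21 and Tnfrsf22 by 1.32 ± 0.21. Adjusted p was between 0.023 and 0.025 for these genes, and their differences had the same sign at both times.

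In all, 673 of 7652 genes passed the limma test, 331 higher and 342 lower on the arrays labelled LIXs. Of these, 281 also differed by at least 2-fold, 119 higher and 162 lower. At an unadjusted p under 0.05 the count was 2235, and the effect of time in the same fit passed for 0 genes. With 1 residual degree of freedom the count depended on the settings, from 0 without the time block, at the more permissive detection level or without a filter on dim probes to 1669 without background correction. Without the array labelled LIXs at 24 h and without the block it was 0, with 638 genes at an unadjusted p under 0.05.

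At 24 h of Dox, the array labelled LIXs stood apart by pancreatic genes. Clps, the cofactor of pancreatic lipase, was 12.4-fold higher than on the array labelled WT, with intensities of 1744 and 226, and Reg1, Pnliprp1, Try4 and Rnase1 were higher by 3.64, 3.47, 3.46 and 3.20 on the log2 scale. Cpb1, Cela2a, Zg16, Ctrb1 and Ctrl completed the 10 largest increases with 3.11, 3.10, 3.05, 3.03 and 2.94. Try5 was at least 10.8-fold higher, Ins2, an insulin gene of pancreatic islets, at least 10.5-fold, Sycn 6.36-fold, Ctrc 4.73-fold and Pla2g1b 4.55-fold, all as lower bounds. Without background correction the bounds for Try5 and Ins2 were 3.74-fold and 3.66-fold, and of the 50 bounds given over all comparisons 36 went from at least 2-fold to below it. Of 14 acinar genes 12 were at least 2-fold higher, with a median of 2.98 (95% interval 2.69 to 3.20).

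ER genes were lower on the array labelled LIXs at this time, with list medians of -0.82 for chaperones, -0.52 for ER-associated degradation, -0.87 for translocation, -0.85 for trafficking and -0.64 for N-glycosylation, each at percentile 0 to 0.21. Fkbp11, an ER prolyl isomerase, was 3.67-fold lower, with intensities of 2402 and 8565. The pancreatic signal and these lower ER values were present on the same array. The largest decreases were those of Ica1 at -2.65, Slc38a10 at -2.39, Asb16 at -2.39, Poc1b at -2.31, Lrtm1 at -2.28, Lrriq3 at -2.23, Aqp4, a water channel, at -2.22, Ccdc134 at -2.20, Camk2n2 at -2.18 and Nelfe at -2.15. Kbtbd13 was at least 3.56-fold lower, Lmntd2 3.17-fold, Capn5 2.99-fold, Zfp933 2.86-fold and Ppp1r27 2.72-fold, again as lower bounds. These bounds ran from 1.48-fold to 1.72-fold without background correction. Xenobiotic (0.64), gluconeogenesis (0.62), bile acid (0.62), glycogen (0.61) and clock genes (0.69) had medians at percentile 99.6 or above, and female-biased genes one of 1.30 at percentile 100. Of 8040 genes, 694 differed by at least 2-fold, 299 higher and 395 lower, with no replicate check. Without background correction the count was 255.

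**Figure D2:**
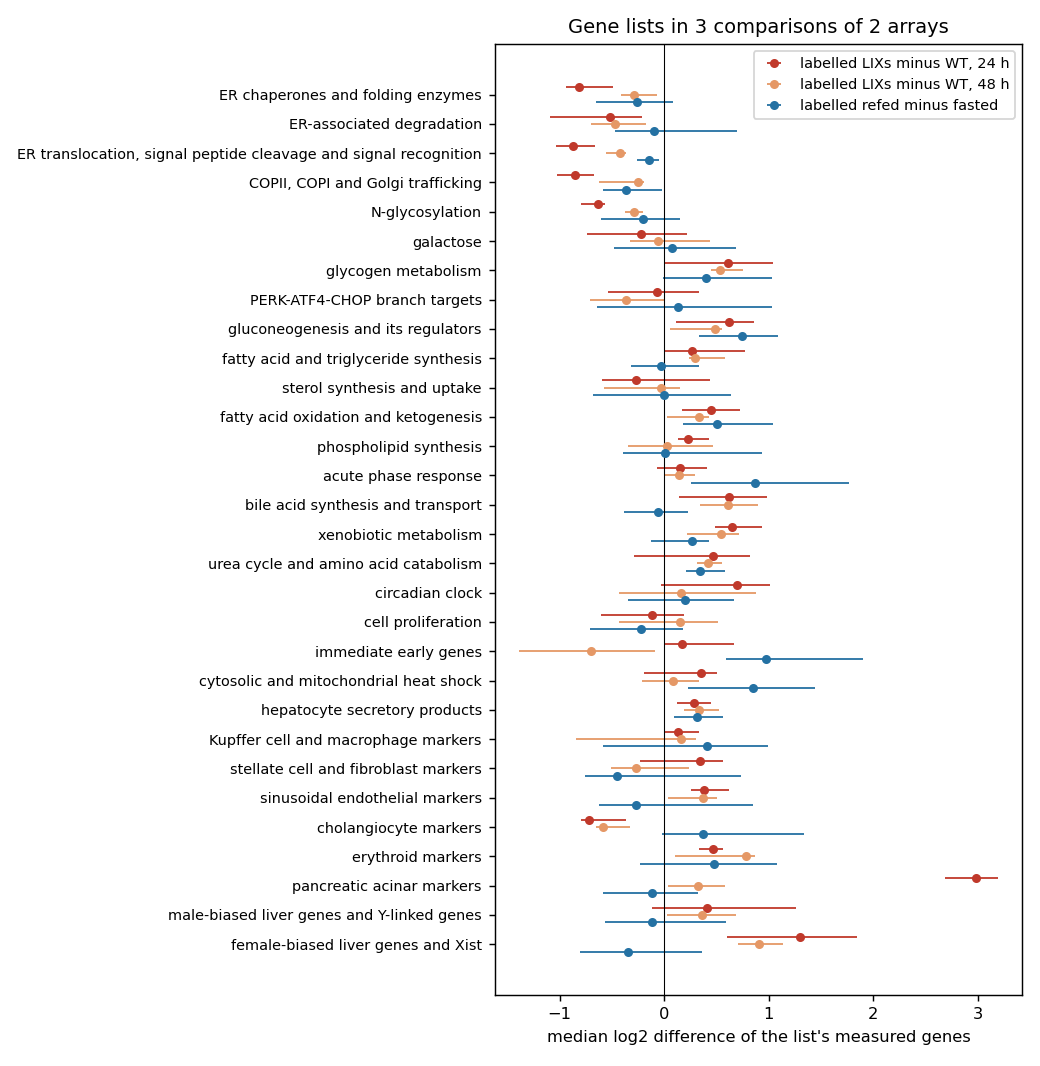
Median log2 difference of the measured genes of each list (points) with its 95% bootstrap interval over genes (lines), for the arrays labelled LIXs minus WT at 24 h and 48 h and for refed minus fasted. The ER lists lie below 0 in both LIXs comparisons (chaperones -0.82 and -0.29), and the acinar list stands at 2.98 at 24 h and 0.33 at 48 h.

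At 48 h of Dox, Kdelr3 had the largest decrease on the array labelled LIXs, with a log2 difference of -2.17. It was followed by the insulin receptor substrate Irs3 at -1.96, Plcxd1 at -1.84 and the histone methyltransferase Dot1l at -1.81. Bhlha15 stood at -1.78, Ddit3 at -1.77, Atf3, a stress-induced transcription factor, at -1.73, Phlda2 at -1.72, Rassf1 at -1.72 and Slc7a7 at -1.70. Stambpl1 was at least 2.86-fold lower, Cdkl2 2.46-fold, Noc3l 2.37-fold, Sgcb 2.32-fold and Epha2 2.31-fold, as lower bounds. These bounds depend on the background step and ran from 1.37-fold to 1.52-fold without it. The ER lists had medians of -0.29 for chaperones, -0.47 for ER-associated degradation, -0.43 for translocation, -0.25 for trafficking and -0.29 for N-glycosylation, at percentiles from 0 to 1.37. Immediate early genes had a median of -0.70 at percentile 0.07, with Ier3 at -1.49 and Fos at -1.39, and the targets of PERK, ATF4 and CHOP one of -0.37 at percentile 0.32. For these genes the array labelled WT at 48 h differed from the one at 24 h. Atf3 read 163 and 546 on the arrays labelled WT at 24 h and 48 h, against 169 and 230 on those labelled LIXs, and Ier3 223 and 630, against 229 and 284.

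Higher on the array labelled LIXs at 48 h were Dnaic1 at 1.69, Mmd2 at 1.64, Extl1 at 1.55, Abca9 at 1.55, Depp1 at 1.39, Rgs16 at 1.38, the tight junction gene Cldn1 at 1.37, Ptges2 at 1.36, Ciart at 1.35 and Mycl at 1.35. St3gal4 was at least 2.46-fold higher, Rab17 2.21-fold, Fabp5 2.20-fold, Entpd2 2.20-fold and Mrnip 2.10-fold, as lower bounds. These bounds depend on the background step and ran from 1.31-fold to 1.41-fold without it. Bile acid (0.61), xenobiotic (0.55), glycogen (0.53), gluconeogenesis (0.49) and female-biased genes (0.91) again had medians at percentile 99.7 or above, whereas the clock median was 0.16 at percentile 78.9. Acinar genes had a median of 0.33 (95% interval 0.04 to 0.58), with 0 of 14 at least 2-fold higher. Of 8105 genes, 329 differed by at least 2-fold, 129 higher and 200 lower, with no replicate check. Without background correction 42 did, 10 higher and 32 lower.

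The difference at 24 h was repeated in part at 48 h. Of 284 genes at least 2-fold higher at 24 h, 261 were also higher at 48 h, and of 382 at least 2-fold lower, 355 were also lower. At 2-fold in both comparisons there were 34 higher and 40 lower genes, against 4.36 and 8.73 for independent lists. Across 7486 genes, which are not independent replicates, the differences correlated with Pearson's r = 0.55 and Spearman's rho = 0.57, and the pairs share no array. Without a filter on dim probes r was 0.40. Between the times, the difference of Lrtm1 increased by 2.71, that of Dnaic1 by 2.04, that of the kinase gene Sgk2 by 2.01, that of Poc1b by 1.97 and that of Armcx3 by 1.92. The pancreatic genes Reg1, Pnliprp1, Cel, Cela3b and Clps had the opposite change, -3.33, -3.20, -3.05, -3.02 and -3.01. These changes between times were not tested.

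**Figure D3:**
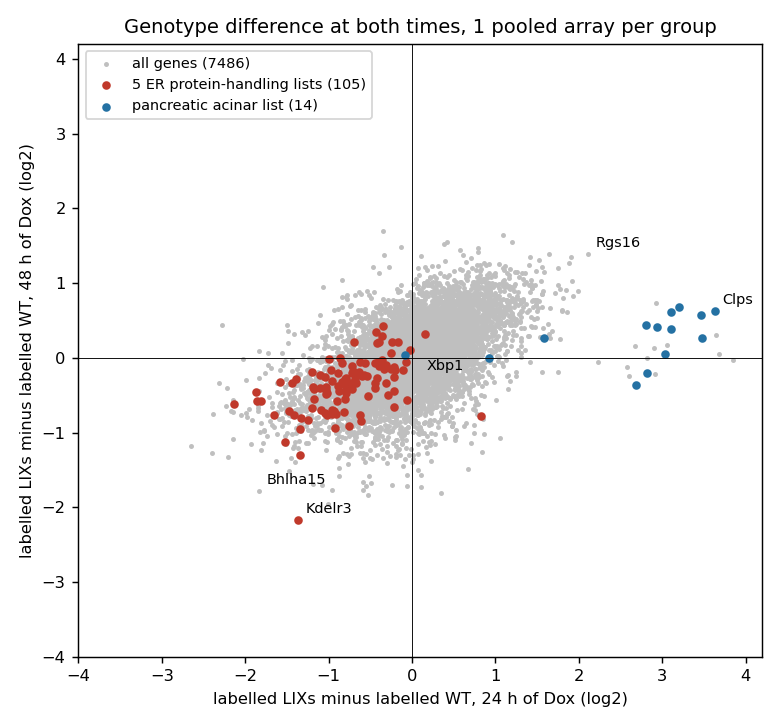
Log2 difference between the arrays labelled LIXs and WT at 24 h (horizontal) against 48 h (vertical), 1 point per gene (7486), with the 105 genes of the 5 ER lists and the 14 acinar genes in colour. Points follow a common diagonal (r = 0.55), most ER genes lie in the lower left, and acinar genes such as Clps lie far to the right with smaller values on the vertical axis (3.64 and 0.63).

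WT mice refed for 2 h after fasting or fasted for 24 h served as nutritional controls. The array labelled refed was higher in acute phase, heat shock and immediate early genes, and in some neutrophil genes. Saa3, an acute phase serum amyloid, was higher by 3.95, with intensities of 8512 and 638 on the arrays labelled refed and fasted, and S100a8, a neutrophil protein gene, by 2.43. Nnmt (2.65), the iron regulator Hfe (2.47), Irf2bp2 (2.44), the complement gene C8a (2.41), haem oxygenase Hmox1 (2.37), Gstt3 (2.36), Ercc5 (2.34) and Cpn2 (2.33) completed the largest log2 differences. Which array stood apart differed by gene. Saa3 stood out on the refed array, against 843 to 1575 on the Dox arrays. C8a stood out on the fasted array, at 272 against 791 to 1265 on all others. Hfe also read lowest there, at 129 against 230 to 306. That value lies at the detection level, and the 1 other detected Hfe probe went the other way. As lower bounds, Serpina7 was at least 8.14-fold higher, Slc16a5 6.77-fold, Pafah1b1 6.04-fold, Igfbp1, a gene known to be induced by fasting, 5.47-fold and Ngef 5.22-fold. Without background correction these bounds were 3.02-fold, 2.63-fold, 2.42-fold, 2.26-fold and 2.19-fold in that order.

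By list, the acute phase median was 0.87 (95% interval 0.26 to 1.77, percentile 100), with Orm2 at 2.15 and Lcn2 at 2.01. Immediate early genes had a median of 0.97, with Egr1 at 2.23, and heat shock genes one of 0.85, with Hspd1 at 2.23, both at percentile 99.9 or above. The 6 neutrophil genes had a median of 1.57, with an interval of -0.10 to 2.48. Gluconeogenesis and fatty acid oxidation genes, which fasting is known to raise, were also higher on the array labelled refed. Their medians were 0.74 (95% interval 0.33 to 1.09) and 0.50 (0.18 to 1.04), at percentiles 99.9 and 100, with Slc37a4 at 2.06, Ppargc1a at 1.13, Ehhadh at 1.69 and Angptl4 at 1.33. Because this runs against the known course of fasting, the direction is that of the labels only. Fatty acid synthesis and sterol lists, which refeeding is known to raise, had medians of -0.03 and -0.01 at percentiles 64.5 and 67.1.

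Lower on the array labelled refed were the sterol enzyme Mvd (-2.31), Tspan33 (-2.25), the transcription factor Stat6 (-2.07), Wdr13 (-1.96) and the olfactory receptor Olfr538 (-1.95). Sec22c (-1.93), Cela2a (-1.90), Srp19 (-1.84), Arfip2 (-1.82) and Ube2dnl2 (-1.79) followed. The other detected probes of Sec22c (1) and Arfip2 (2) went the other way. As lower bounds, Slc25a36 was at least 4.73-fold lower, Trp53rka 4.50-fold, Dkkl1 4.31-fold, Pyurf 4.13-fold and the calcium channel gene Cacna1a 4.03-fold. These bounds ran from 1.85-fold to 2.05-fold without background correction. Cacna1a stood out on the fasted array, at 240 against 108 to 116 on all others. By contrast, Srp19 read 132 on the refed array and 184 to 290 on all others. ER lists had medians between -0.37 and -0.10, at percentiles from 4.04 to 52.4. Of 8856 genes, 2142 differed by at least 2-fold, 1089 higher and 1053 lower, with no replicate check, and the median of all genes was -0.09. Without background correction 255 did, 183 higher and 72 lower.

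Whether the LIXs difference resembles the refed difference was compared over 7128 genes. The averaged difference correlated with refed minus fasted at r = 0.19 and rho = 0.20 across genes, without shared arrays. Depp1 and G6pc were higher in both, with refed minus fasted differences of 1.51 and 0.61, whereas Cyp3a11 was higher on the arrays labelled LIXs and at -1.33 in refed minus fasted. Of the 318 genes that rose, 60 were at least 2-fold higher on the array labelled refed, against 42.8 for independent lists, and 10 were lower, against 19.9. Of the 313 that fell, 50 were at least 2-fold lower, against 19.5, and 15 were higher, against 42.1. The sign of the correlation and the side of these overlaps follow the labels of both comparisons, and each would turn if the labels of only 1 of them were exchanged.

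The pair of WT arrays at 48 h and 24 h shows how far arrays with the same genotype label stood apart. Immediate early and stress genes were higher on the array labelled WT at 48 h, with Atf3 at 2.69, Ier3 at 2.05, Ddit3 at 1.59 and Fos at 1.35. The immediate early list had a median of 1.10 at percentile 100, with 7 of 9 genes at least 2-fold higher, and the targets of PERK, ATF4 and CHOP one of 0.46 at percentile 100. Tnfrsf12a (2.45), Hilpda (2.44), Cdr2 (2.30), Pdk4, which restrains glucose oxidation (2.28), Ptpn14 (2.24), the chemokine Ccl4 (2.20), Rassf1 (2.20), Mllt11 (2.15) and Stx3 (2.09) were the other largest increases. Lower were Lrtm1 (-2.68), Dnaic1 (-1.87), the glucose transporter Slc2a2 (-1.81), Aqp4 (-1.72), Nipal3 (-1.60), Zap70 (-1.58), Cited2 (-1.54), Sgk2 (-1.49), Poc1b (-1.45) and Hspb6 (-1.44). ER chaperones had a median of -0.26 and trafficking genes one of -0.24, at percentiles 0.18 and 0.10. As bounds, Dusp8 was at least 4.01-fold higher, Spsb1 3.59-fold, Nup50 3.01-fold, Cyb561 2.69-fold and Noc3l 2.37-fold. Arap1 was at least 3.46-fold lower, Zfp933 2.86-fold, Ccnl2 2.45-fold, Recql5 2.28-fold and Tapbp 2.19-fold. All these bounds ran from 1.34-fold to 1.85-fold without background correction. Of 8071 genes, 303 differed by at least 2-fold, 198 higher and 105 lower, and time and pool cannot be separated. Without background correction 56 did.

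Between the arrays labelled LIXs, pancreatic genes were lower at 48 h than at 24 h. Ins2 differed by -3.05, Ctrb1 by -3.02, Cela3b by -2.81, Reg1 by -2.73, Cpa1 by -2.68, Cel by -2.67, Zg16 by -2.63, Cela2a by -2.63, Pnliprp1 by -2.60 and Clps by -2.56. The acinar median was -2.55, with 12 of 14 genes at least 2-fold lower. ER genes were higher at 48 h, with medians of 0.40 for chaperones, 0.25 for ER-associated degradation, 0.28 for translocation, 0.29 for trafficking and 0.26 for N-glycosylation, at percentile 99.1 or above. Tubb2b (1.53), Slc38a10 (1.52), Ica1 (1.46), the fatty acid hydroxylase gene Cyp4a14 (1.45), Dynll1 (1.32), Hilpda (1.31), Saa2 (1.27), Mob3a (1.26), Cdr2 (1.24) and Camk2n2 (1.21) were the largest increases. As bounds, Kbtbd13 was at least 2.16-fold higher, Mns1 2.00-fold, Slc16a6 1.98-fold, Rbfox2 1.96-fold and Timp1 1.80-fold. Ctrc was at least 4.73-fold lower, Pdia2 3.68-fold, Dmbt1 2.91-fold, Pnliprp2 2.12-fold and Reg2 2.11-fold. These bounds were 2.05-fold for Ctrc and from 1.23-fold to 1.75-fold for the others without background correction. Female-biased genes had a median of -0.78 at percentile 0, with Sult2a2 at -1.89. Of 8001 genes, 106 differed by at least 2-fold, 40 higher and 66 lower, with no replicate check. Without background correction 28 did, 5 higher and 23 lower.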

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

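The tests of explanations in this part were chosen after the results had been seen. Several named genes and list medians had differences of opposite sign between the arrays labelled LIXs and WT at 24 h and 48 h of Dox. Each time has 1 array per genotype, so the difference was not tested. Values below are the 48 h difference minus the 24 h difference on the log2 scale, after the differences at 24 h and 48 h.

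Of the pancreatic genes detected on all 4 Dox arrays, Cel went from 2.69 to -0.37 (-3.05) and Cela3b from 2.81 to -0.21 (-3.02), while 11 of 14 acinar list genes were above 0 at 48 h. Among other genes detected on all 4, Lrtm1 went from -2.28 to 0.44 (2.71), Dnaic1 from -0.35 to 1.69 (2.04) and Armcx3 from -1.83 to 0.09 (1.92). The stress gene Atf3, which was high on the array labelled WT at 48 h, went from 0.11 to -1.73 (-1.84) and Dot1l from 0.34 to -1.81 (-2.16). Ins2, Ctrc, Mrnip and Noc3l were below the detection level on at least 1 of these arrays, so their values are set partly by background and show no opposite directions. They are 3.85 and -0.03 (-3.88) for Ins2, 2.60 and -0.24 (-2.83) for Ctrc, -0.47 and 1.21 (1.68) for Mrnip, and 0.84 and -1.25 (-2.09) for Noc3l.

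Among the lists, the immediate early median went from 0.17 (95% interval -0.00067 to 0.67) to -0.70 (-1.39 to -0.09), that of 3 neutrophil markers from 0.21 (-1.16 to 0.26) to -0.62 (-0.98 to -0.52) and that of stellate cell markers from 0.34 (-0.23 to 0.56) to -0.27 (-0.51 to 0.24), changes of -0.87, -0.83 and -0.61. The proliferation median went from -0.12 (-0.60 to 0.19) to 0.15 (-0.43 to 0.52), a change of 0.27. The intervals of these 4 lists include 0 at 24 h, and those of the stellate cell and proliferation lists also at 48 h, so opposite directions are not established for them. These intervals cover genes and not arrays, so one that excludes 0 would not establish a direction for a genotype either. Lymphocyte markers went from 0.29 to -0.50 (-0.79), over 3 measured genes at 24 h and 2 at 48 h. No group has more than 1 array, so single arrays could not be compared with others of their group.

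As a list, pancreatic genes stood high on 1 array, that labelled LIXs at 24 h. An effect of the transgene that lasts to 48 h at the size seen at 24 h is argued against by the 48 h pair, where the acinar median was 0.33 (95% interval 0.04 to 0.58). On the array labelled LIXs at 24 h Amy2a5 read 19880 and Cela2a 4270, against 10521 and 580 on the array labelled WT, and 9 of the 14 list genes were above the detection level on all 6 arrays. Cela2a also read 1367 on the fasted array against 435 on the refed array. The acinar median of refed minus fasted was -0.11 (95% interval -0.59 to 0.32). Pancreatic tissue taken with the liver and a transient effect of the transgene at 24 h were not tested against each other, and both stay open.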

How the results depend on the processing

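The saddle-point fit and the inclusion of unnamed probes were chosen after the data had been seen. Neither correlation changed sign under an alternative, nor did a list median of the averaged, 24 h, 48 h or refed comparison whose interval excluded 0. The same held for the 20 genes named by rank for the averaged comparison and 77 further list genes past its test. It also held for the 100 ranked and 50 lower-bound results of comparisons of 2 arrays. For single genes most alternatives could hardly turn a sign, so this is a weak check. Detection, filter, block, prior and adjusted p leave a gene's difference as it was. Background settings and offset act nearly alike on arrays with such similar sorted values. Only the mean of probes and left-out or added arrays could readily turn one. Other named values were not recomputed, and the ER lists kept medians below 0 in both LIXs comparisons. The count of 673 genes in the averaged comparison was the least stable value. It was 1669 without background correction (593 shared with the 673), 1281 with an offset of 50 (628 shared), 1506 with the saddle-point fit (673 shared), 1432 with an intensity trend in the prior (665 shared) and 1387 at an adjusted p of 0.10. Limma called 0 genes at the detection share of 0.05 (2233 at an unadjusted p under 0.05, smallest adjusted p 0.0511), without a filter on dim probes (2918, 0.140), without the time block (1810, 0.104) and with the fasted and refed arrays added as WT (373, 0.860). Leaving out 1 Dox array, without the block and with the lone array assumed to vary like the other genotype, gave from 0 to 287 genes: 0 without the array labelled LIXs at 24 h, 247 without WT at 24 h, 23 without LIXs at 48 h and 287 without WT at 48 h. The mean of probes (642), a robust prior (615) and unnamed probes (645) stayed within 1.5 times. No paired analysis was possible because the labels give no replicate numbers beyond 1 pool per group, and time is already the block of the averaged comparison. The 20 genes named by rank for the averaged comparison and the 77 list genes all missed the adjusted p wherever the count was 0, as did 19 of the 20 without the array labelled LIXs at 48 h, 5 without WT at 48 h and 1 with the mean of probes. Of the 77 list genes, 69 missed it without LIXs at 48 h, 68 without WT at 24 h, 51 without WT at 48 h, 13 with the robust prior, 11 with unnamed probes, 8 with the mean of probes and 1 without background correction. The cause was not tested.

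Counts at 2-fold depended on the background, because less subtraction shrinks the differences of dim genes. Without correction they were 255 at 24 h, 42 at 48 h, 255 for refed minus fasted, 56 for WT and 28 for LIXs between times. With an offset of 50 they were 404, 103, 702, 121 and 42 in that order, with 424 higher and 278 lower for refed minus fasted. The saddle-point fit gave 173 at 48 h, 175 for WT and 60 for LIXs. Of the 100 ranked results 22 were below 2-fold without correction, 7 with the mean of probes and 3 with an offset of 50, and 36, 7 and 23 of the 50 lower bounds went below it in these settings, as did 17 with the saddle-point fit. At 1.5-fold the 5 counts were 2433, 2001, 4664, 1594 and 931. The correlation between times was 0.64 without correction, 0.61 with an offset of 50, 0.58 with the saddle-point fit, 0.51 at the detection share of 0.05 and 0.40 without a filter. That with refed minus fasted was 0.25, 0.22 and 0.13 without correction, with an offset of 50 and without a filter.

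Medians of lists that left their interval were as follows. Without correction the averaged medians were -0.49 for translocation, -0.40 for N-glycosylation, 0.19 for endothelial, -0.10 for neutrophil and 1.0 for acinar genes. At 24 h they were -0.64 for translocation, -0.53 for N-glycosylation, 0.41 for xenobiotic, 0.083 for lymphocyte and 1.89 for acinar genes, and at 48 h 0.32 for glycogen, 0.31 for amino acid catabolism, -0.30 for neutrophil and 0.38 for female-biased genes. With an offset of 50 they were -0.12 for neutrophil genes averaged, -0.56 for N-glycosylation, 0.15 for lymphocyte and 2.39 for acinar genes at 24 h, and 0.41 for glycogen, -0.44 for neutrophil and 0.61 for female-biased genes at 48 h. Without a filter they were -0.047 for cholangiocyte and -0.11 for neutrophil genes averaged, -0.019 for cholangiocyte, 0.014 for lymphocyte, 0.34 for erythroid and 0.32 for female-biased genes at 24 h, and -0.076 for cholangiocyte and -0.18 for neutrophil genes at 48 h. The mean of probes gave 0.071 for phospholipid genes at 24 h. The saddle-point fit gave 0.20 for lymphocyte and 2.60 for acinar genes at 24 h, and -0.47 for neutrophil and 0.65 for female-biased genes at 48 h. On 1 array the level of a gene near the detection level of 129 is set by background more than by RNA, which limits statements about dim genes.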

Other observations

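The tests of explanations in this part were chosen after the results had been seen. Set against the mean of the refed and fasted WT arrays, the genes of the 5 ER lists stood at different levels on the 2 kinds of Dox array. On the arrays labelled WT, 91 of 105 ER genes were above that mean, and on the arrays labelled LIXs 51 were. Bhlha15 read 702 and 824 on the arrays labelled WT at 24 h and 48 h, against 264 and 306 on those labelled LIXs and 321 and 332 on the refed and fasted arrays. Dnajc3 read 2081 and 2368, against 784 and 1138, and 913 and 842. Hspa5 did not follow its list, with intensities between 180 and 240 on all arrays.

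Lower ER genes on the arrays labelled LIXs run against the known action of Xbp1s. Pancreatic RNA on the arrays labelled WT, rich in ER transcripts, is argued against by acinar genes, which were higher on the array labelled LIXs at 24 h by a median of 2.98 (95% interval 2.69 to 3.20) and at 48 h by 0.33 (0.04 to 0.58). A lowering by the transgene below the level of the refed and fasted WT arrays, for which the labels give no Dox time, stays open. The ER median of the array labelled LIXs was -0.29 (-0.44 to -0.042) at 24 h and 0.026 (-0.21 to 0.29) at 48 h relative to the fasted array. Relative to the refed array it was -0.087 (-0.15 to 0.029) and 0.26 (0.18 to 0.31). The arrays labelled LIXs differed from each other by 0.27 and those labelled WT by -0.16. An exchange of the genotype labels at both times is a candidate explanation, since the arrays labelled WT stood 0.61 (0.49 to 0.71) above the mean of the refed and fasted arrays. But the refed and fasted arrays differ in feeding, and the labels give no Dox time for them. A lowering from a level that Dox or feeding had raised therefore stays open too.

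Fasting genes were higher on the array labelled refed than on the array labelled fasted. Exchanged labels would put gluconeogenesis and fatty acid oxidation high and fatty acid and sterol synthesis low, and 2 of these 4 lists lay where an exchange would put them, since both synthesis lists stood near random lists. An exchange and a response of the pool labelled refed therefore cannot be told apart on 1 array per group. That pool also carried high acute phase genes such as Saa3 and some high neutrophil genes. The fasted array in turn stood apart for some genes, such as Slc2a2 at 138 against 276 to 856 on all others. A departure of the fasted array was not tested. No biological explanation was tested.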
